A study of Fusarium verticillioides with 6 samples.

How the data were processed

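RNA sequencing was done on mycelium of Fusarium verticillioides, a fungus that infects maize. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was checked on a Bioanalyzer, and libraries were made with a VAHTS Universal V6 RNA-seq kit. The samples fell into 2 groups of 3 by their labels: mycelium treated with luvangetin, a coumarin from the plant Zanthoxylum avicennae, and untreated mycelium. Dose, exposure time and growth conditions are not given in the sources used here. The second group is labelled only as untreated, so luvangetin itself cannot be told apart from anything else that came with the treatment. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series' design text calls the samples of a group replicates and says no more of their origin.

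The authors deposited 1 table of FPKM values (fragments or reads per kilobase of exon, scaled to the counted reads of each sample) for 14134 genes in 6 columns. The column names begin with Fo where the sample labels have Fv; each column was matched to the only label with the same ending, and 0 columns were left unused. The aligner, the counting program, the genome build, the strand setting and any filter are not given in the sources used here. No gene in the table is at 0 in all samples, so genes without reads in any sample are not listed. The genes carry locus tags and no names. All 14134 tags occur in an NCBI RefSeq gene table of assembly ASM14955v1, which has 16290 genes, but for these genes it repeats the tag in place of a symbol, in 14134 of 14134 cases. That table was used for gene order and gene length. No coordinates are given, since no source names the build behind the deposited values.

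Whole reads could be recovered from the deposited FPKM values. For each gene, the largest exonic length up to the annotated gene length was sought at which the values of all 6 samples are whole numbers of reads, within a relative tolerance of 3e-09. This succeeded for 14134 of 14134 genes (100% of the genes). The library totals behind the FPKM values came out as whole numbers too, at 43477076 to 44305995 reads per sample. For 464 genes the 6 read numbers share a factor above 1, so their true number may be smaller by that factor. The recovered reads summed to between 1.11% and 1.46% more than the library totals, and this doubt applies to shares of reads but not to fold changes. In simulated tables, 99.6% of 13888 genes and 6 of 6 library totals were recovered exactly.

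The main test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with the deposited scaling, an empirical Bayes variance with a mean trend and robust estimation, and Benjamini-Hochberg adjustment at 0.05. All 6 samples entered the fit, without a replicate block. Genes were tested if FPKM was at least 1 in at least 3 samples, which left 8718 genes. Fold changes from the fit are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Every adjusted p of a single gene comes from limma. On simulated reads for the real genes, with 200 planted changes of mixed size and 8793 genes in the fit, the test recovered 74% of 1.25-fold, 93.9% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes, and 7.65% of its calls were unchanged genes. The planted rises and falls were balanced and there was no common shift, unlike in the real data. These rates therefore do not carry over to calls that rest on the scaling.

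Gene lists for pathways and cell functions had been fixed before the data were examined as patterns on product names: 38 lists and 8 single products. They matched 0 genes, because neither the deposited table nor the reference table gives products, so no list could be tested. The range of locus tags FVEG_00315 to FVEG_00329, fixed beforehand as the place of the fumonisin cluster from general knowledge of the species, was used as the only list. The rule for named genes, also fixed beforehand, asked for product names in most of its parts. What remained of it were the 2 rising and 2 falling genes of largest change among those past the threshold, with no overlap between groups and a mean of at least 10 FPKM in the higher group, and up to 4 loci of the fumonisin range by highest mean. Other loci in the text were chosen after their values were seen, and this is said where they appear.

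Neighbouring genes were taken in the order of the reference table among tested genes placed on a chromosome. The number of adjacent pairs in which both genes rose or both fell at least 2-fold was compared with 10000 random reassignments of the calls. Shares of reads were compared by exact two-sided permutation tests over samples, for which 3 samples against 3 cannot give a p below 0.1. Intervals from read numbers are exact 95% binomial intervals and cover only the counting error of independently counted reads. A gene of 100 to 1000 reads summed over a group had a median coefficient of variation of 10.9% among luvangetin samples and 11.3% among untreated ones, against 1.05% and 1.20% for genes above 100000 reads.

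Alternatives fixed before the data were examined were 2 other pseudocounts (0.1 and 0.5), no filter on low values, a mean of at least 5 FPKM, rescaling to 1000000 per sample, median-of-ratios scaling, quantile normalization, a variance model without trend and robust estimation, a replicate block, and leaving out each sample in turn. Added after the data were seen were limma-voom on the recovered reads, with the deposited library totals and with median-of-ratios scaling, and 2 other ways to compute shares of reads. Computations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.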

Results

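The transcriptomes of 6 mycelium samples of Fusarium verticillioides were compared, 3 treated with luvangetin and 3 untreated, to find which genes differ between these groups. The libraries held 43477076 to 44148341 counted reads in the luvangetin group and 43662809 to 44305995 in the untreated group. Of 14134 listed genes, 12700 ± 11.5 (SD, n = 3) had reads in a luvangetin sample and 13095 ± 18.0 (SD, n = 3) in an untreated sample. The first principal component of the 8718 tested genes held 96.4% of the variance and separated the groups. Within a group, the variance of a gene's read numbers averaged 2.10 to 2.33 times that of counting error alone for genes with between 100 and 10000 reads. For genes above 100000 reads this mean ratio of variances was 43.1 (luvangetin) or 17.9 (untreated). The median coefficient of variation of those genes was 1.05% and 1.20%. No pair of samples within a group agreed within the noise of independently counted reads (mean chi-square of 2.42 to 3.60 per gene where 1 is expected). Whether the reads were counted independently of each other is not known. No samples were merged, which does not show whether they came from separate cultures.

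In luvangetin samples more of the reads came from fewer genes. The 10 genes with most reads held 21.4% ± 0.120 (SD, n = 3) of the reads in luvangetin samples and 16.4% ± 0.0103 (SD, n = 3) in untreated samples. The 100 genes with most reads held 51.4% ± 0.172 (SD, n = 3) against 41.1% ± 0.0669 (SD, n = 3), and the top 1000 held 83.7% ± 0.0957 against 76.6% ± 0.0452. The effective number of expressed genes, the exponential of the Shannon entropy of the read shares, was 744 ± 5.99 (SD, n = 3) under luvangetin and 1227 ± 4.18 (SD, n = 3) without it. The median FPKM of a listed gene was 1.72 ± 0.0182 against 2.90 ± 0.0170. In each of these 5 measures the groups did not overlap, with an exact two-sided permutation p of 0.1 (0.1 after Benjamini-Hochberg adjustment over the 5), the smallest that 3 samples against 3 allow.

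**Figure D1:**
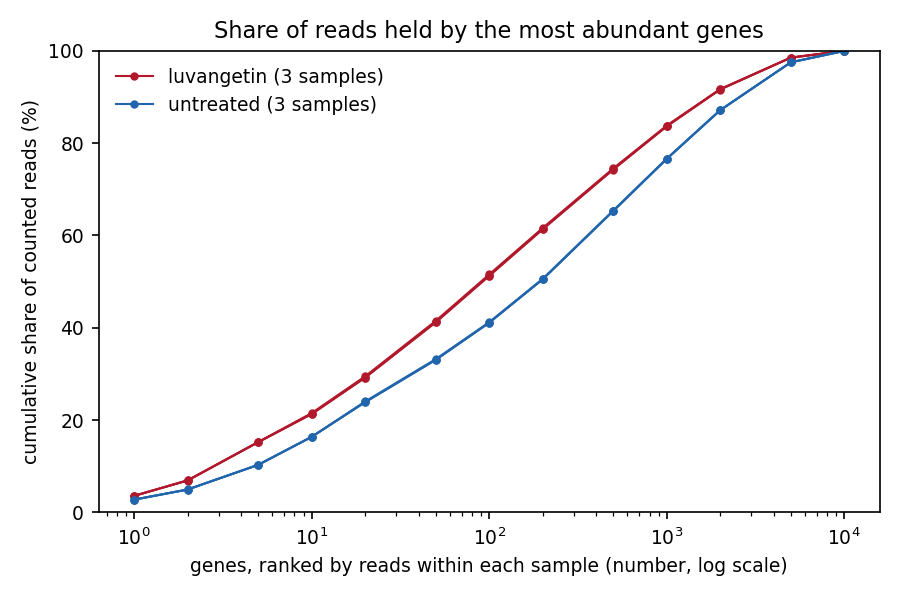
Cumulative share of counted reads (%, vertical axis) held by the most abundant genes (number of genes on a log scale, horizontal axis), with 1 line per sample and luvangetin in red, untreated in blue. The 3 lines of each group lie on top of each other, and at 100 genes the luvangetin samples reach 51.4% and the untreated samples 41.1% on average.

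The abundant genes did not all move the same way. Among the 100 genes with most reads over all samples, 68 rose, 29 fell and 3 did not pass the test, with log2 changes from -1.31 to 2.67; with median-of-ratios scaling, which removes the shift shared by most genes, 91 were higher and 8 lower. Of the 10 genes with the highest mean FPKM, 8 rose, 1 fell and 1 did not pass the test, and all 10 were higher with median-of-ratios scaling. Some of the 8 rises did not hold in every alternative. FVEG_09122, FVEG_02993 and FVEG_11374 had lowest log2 changes over all fits of -0.15, -0.11 and -0.30. Their adjusted p was under 0.05 in every fit (limma), so each was also called a fall. FVEG_02331 lost its call in an alternative (highest limma adjusted p 0.128). The locus with the highest FPKM, FVEG_04512, rose from 36948 ± 1285 (SD, n = 3) to 57672 ± 2247 (SD, n = 3), a log2 change of 0.64 (SE 0.03, limma adjusted p = 1.05e-07) and of 1.30 with median-of-ratios scaling. Quantile normalization ended this call, since it gives the highest rank the same value in every sample. The locus FVEG_07236 had the largest rise among the 10, from 6490 ± 252 to 13832 ± 308 FPKM (log2 change 1.09, adjusted p = 1.81e-09; 1.75 with median-of-ratios scaling). FVEG_02006 fell, from 27562 ± 127 to 19435 ± 1026 FPKM (log2 change -0.51, adjusted p = 5.33e-07), but its change was 0.15 with median-of-ratios scaling. All loci named in this paragraph were chosen after their values were seen, and no gene name is given for them.

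On the deposited scale, most of the transcriptome was lower in luvangetin samples. Of 8718 tested genes, 1033 rose and 6919 fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg). The median log2 change of all tested genes was -0.55 on the log2(FPKM + 1) scale, a 1.46-fold decrease there. It was -0.66 with voom on the recovered reads. The balance of rises and falls rested on the scaling. Median-of-ratios scaling sets the median change near 0 by construction and gave 3264 genes higher and 3211 lower, and quantile normalization gave 2909 higher and 3454 lower. Of the genes that fell on the deposited scale, 3211 were also lower after median-of-ratios scaling and 1570 were higher. The groups did not overlap in 7926 genes (90.9%), of which 1033 were higher and 6893 lower in luvangetin samples. Chance gives 10% for a single gene. A shift shared by all genes of a sample separates many genes at once, so the 90.9% also reflects the scaling.

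Changes of at least 2-fold were found in 1369 genes, of which 191 rose and 1178 fell. Median-of-ratios scaling moves the change of nearly all genes upwards, so by construction it adds rises and removes falls. The 2-fold counts under that scaling were 546 higher and 237 lower. The numbers also varied with expression level. On the deposited scale, in the highest of 10 expression classes, 63 rose and 65 fell at least 2-fold, with a median log2 change of -0.24. In class 5, counted from the lowest, 6 rose and 157 fell, with a median of -0.66. In the lowest class, 14 rose and 83 fell, with a median of -0.49.

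**Figure D2:**
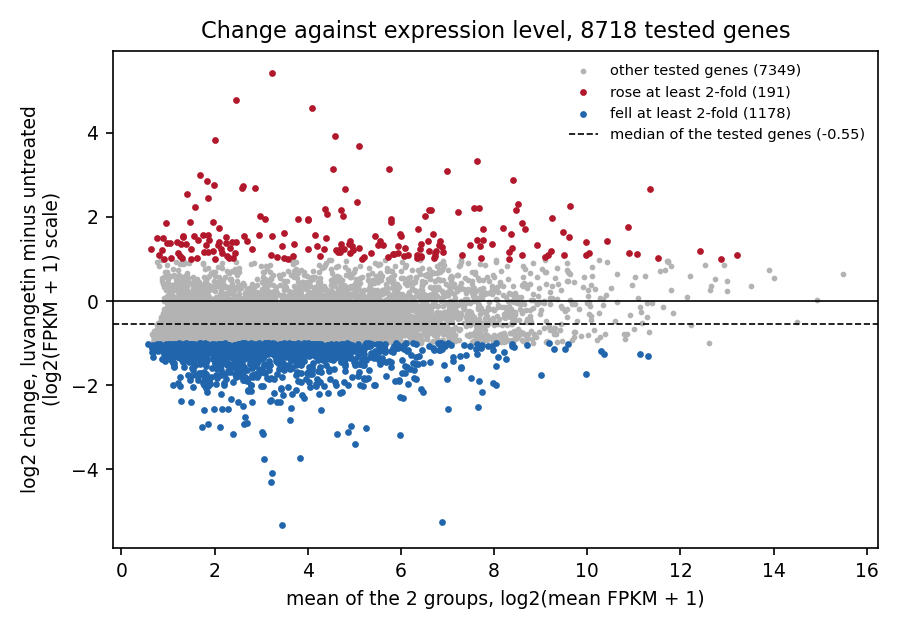
Log2 change of each of the 8718 tested genes (luvangetin minus untreated on the log2(FPKM + 1) scale, vertical axis) against its expression, the mean of the 2 groups' log2(mean FPKM + 1) (horizontal axis), with red for the 191 genes that rose at least 2-fold, blue for the 1178 that fell and grey for the rest. The dashed line is the median change of -0.55, which lies below 0 (solid line), and of the 100 genes with most reads 68 rose and 29 fell on this scale.

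On the log2(FPKM + 1) scale the largest rise among tested genes was at locus FVEG_11089, which was near silent in untreated mycelium at 0.444 ± 0.0890 FPKM (SD, n = 3) and reached 60.5 ± 1.29 FPKM (SD, n = 3) under luvangetin. Its log2 change was 5.41 (SE 0.05, adjusted p = 1.10e-12) and 5.83 with median-of-ratios scaling. The next gene in the reference order, FVEG_11090, chosen after its values were seen, also rose, from 0.0610 ± 0.0608 to 14.2 ± 1.63 FPKM (adjusted p = 1.92e-10). FVEG_13441 rose from 0.0386 ± 0.0334 to 27.8 ± 1.90 FPKM (log2 change 4.79, SE 0.06, adjusted p = 6.25e-12), a log2 change whose size depends on the pseudocount. It had 2 reads in the untreated group and 1435 in the luvangetin group, a read ratio of 722 with a 95% counting interval of 199 to 5966 (exact binomial). By the ratio of mean FPKM the order was the other way, with 136 for FVEG_11089 and 720.0 for FVEG_13441, and it was also the other way with a pseudocount of 0.1 (log2 changes of 6.81 and 7.68).

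The largest falls on that scale were at FVEG_02344 and FVEG_01856. FVEG_02344 fell from 68.3 ± 0.800 to 0.726 ± 0.0845 FPKM (SD, n = 3 each), 94.1 times lower, with a log2 change of -5.33 (SE 0.05, adjusted p = 5.41e-13). FVEG_01856 was an abundant transcript in untreated mycelium at 718 ± 1.89 FPKM and fell to 18.0 ± 0.587 FPKM, 39.8 times lower (log2 change -5.24, SE 0.02, adjusted p = 2.54e-14). With median-of-ratios scaling their log2 changes were -4.86 and -4.60. The deposited table gives no product for any of the 4 loci with the largest changes.

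**Figure D3:**
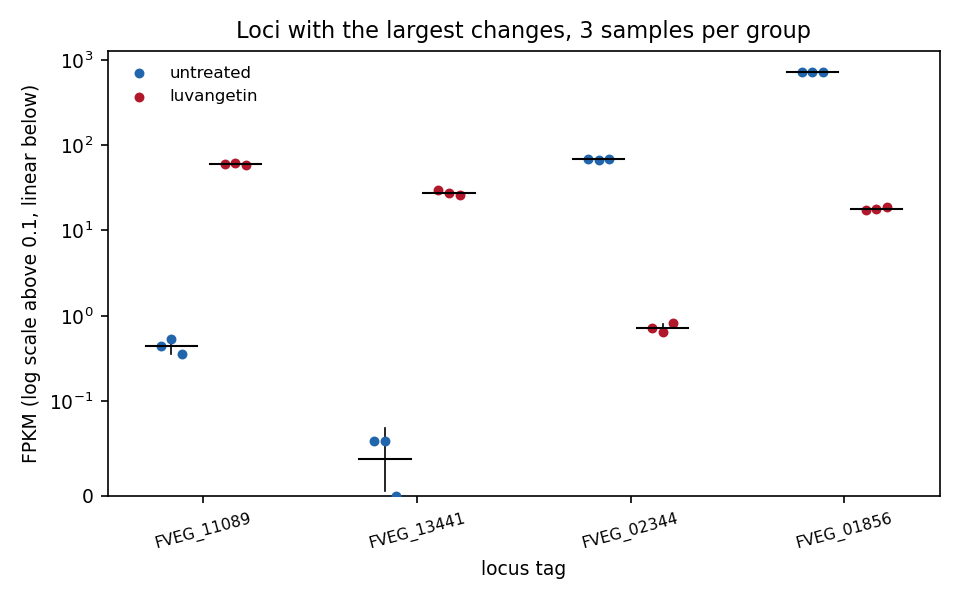
FPKM (vertical axis, log scale above 0.1 and linear below) of the 2 loci that rose most and the 2 that fell most on the log2(FPKM + 1) scale (horizontal axis), with 1 point per sample, blue for untreated and red for luvangetin; horizontal bars are means and vertical bars 1 SD (n = 3). FVEG_01856 went from 718 to 18.0 FPKM and FVEG_11089 from 0.444 to 60.5, and the groups do not overlap at any of the 4 loci.

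The fumonisin range was weakly expressed, and its most abundant transcript fell. Fumonisins are polyketide mycotoxins of this species, made by enzymes encoded side by side. The table lists 13 loci with tags between FVEG_00315 and FVEG_00329, of which 3 reached the expression needed for testing. All 3 fell on the deposited scale (limma, 3 also when adjusted over the list alone). So did 6919 of all 8718 tested genes, so this count does not set the range apart. With median-of-ratios scaling 2 were lower and 0 higher, against 3211 lower and 3264 higher among all tested genes. The other lists fixed beforehand had 0 matching genes. FVEG_00328 fell from 12.7 ± 0.610 to 2.46 ± 0.239 FPKM (SD, n = 3), 5.18 times lower, with a log2 change of -1.99 (SE 0.06, adjusted p = 2.18e-09) and of -1.45 with median-of-ratios scaling. FVEG_00326 fell from 2.56 ± 0.210 to 1.10 ± 0.244 FPKM (log2 change -0.76, SE 0.10, adjusted p = 3.43e-05; -0.35 with median-of-ratios scaling). FVEG_00316 went from 1.29 ± 0.116 to 0.925 ± 0.0625 FPKM (log2 change -0.25, SE 0.07, adjusted p = 0.0103), but with median-of-ratios scaling its change was 0.10 and did not pass the threshold, and with quantile normalization it was 0.22 and passed the threshold as a rise. FVEG_00322, among the 4 loci of highest mean but below the filter, was at 0.703 ± 0.0997 FPKM in untreated and 0.760 ± 0.138 FPKM in luvangetin samples. Of the 10 loci below the filter, 7 had a lower mean under luvangetin, and none exceeded 1.17 FPKM in any sample. In the limma fit without a filter, FVEG_00324, FVEG_00325, FVEG_00327 and FVEG_00329 fell (adjusted p from 0.000166 to 0.0195) and 0 of the 10 rose. In that fit 8197 of all 14134 genes fell, so 4 of 10 is no excess of falls. The means of these 4 loci, picked because they fell in that fit, were also lower after median-of-ratios scaling, a difference that was not tested. The summed FPKM of the range was 20.2 ± 0.624 (SD, n = 3) in untreated and 6.56 ± 0.174 (SD, n = 3) in luvangetin samples, 3.08 times lower, and 1.95 times lower with median-of-ratios scaling. FVEG_00328 made up 10.3 of the 13.7 FPKM by which the groups differed on the deposited scale.

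**Figure D4:**
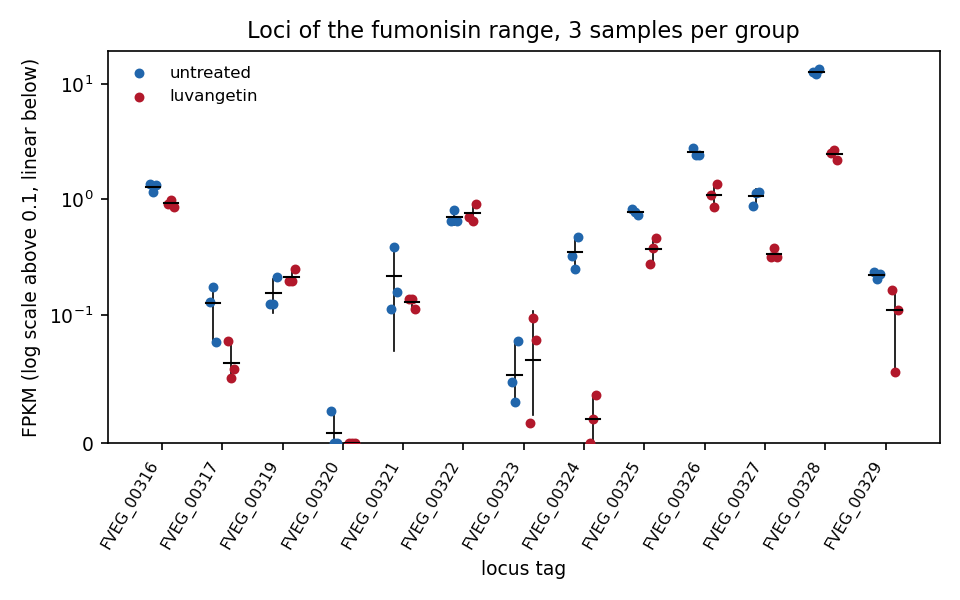
FPKM (vertical axis, log scale above 0.1 and linear below) of the 13 listed loci of the fumonisin range (horizontal axis, by locus tag), with 1 point per sample, blue for untreated and red for luvangetin; horizontal bars are means and vertical bars 1 SD (n = 3). FVEG_00328 stands highest in both groups, at 12.7 FPKM untreated and 2.46 FPKM under luvangetin.

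Genes that changed at least 2-fold lay next to each other more often than chance. By gene order in assembly ASM14955v1, of 8644 adjacent pairs of tested genes, 263 changed at least 2-fold in the same direction, against 162 on average when the calls were reassigned at random (1.63 times; one-sided permutation p = 1e-04, the smallest that 10000 reassignments give). With median-of-ratios scaling the pairs numbered 127, against 40.2 in reassigned calls. The excess was 5.60 times for pairs that both rose and 1.52 times for pairs that both fell on the deposited scale, but 3.02 and 3.94 times with median-of-ratios scaling, so which direction clustered more rested on the scaling. Genes are not independent replicates, so this describes these 6 libraries.

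There were 12 runs of at least 4 neighbouring tested genes that all fell at least 2-fold, and 0 runs of that length that rose. The steepest ran from FVEG_08442 to FVEG_08438 and held 4 tested genes with a median log2 change of -2.36. Within it FVEG_08439 fell from 29.7 ± 1.09 to 1.26 ± 0.0917 FPKM (log2 change -3.76, -3.25 with median-of-ratios scaling, adjusted p = 7.36e-12) and FVEG_08438 from 31.5 ± 0.688 to 3.61 ± 0.156 FPKM (log2 change -2.82, -2.24 with median-of-ratios scaling, adjusted p = 1.17e-11). A run of 5 genes from FVEG_09337 to FVEG_09342 had a median log2 change of -1.77, and its FVEG_09339 fell from 187 ± 2.43 to 41.3 ± 0.279 FPKM (log2 change -2.16, -1.51 with median-of-ratios scaling, adjusted p = 5.41e-13). With median-of-ratios scaling 3 genes in each of these 2 runs were still at least 2-fold lower, and there were 3 rising and 0 falling runs of at least 4 genes. A rising run spanned FVEG_03228 to FVEG_03225. Its member FVEG_03227 was at 9.49 ± 0.538 FPKM in untreated and 42.7 ± 2.85 FPKM in luvangetin samples (log2 change 2.06, 2.68 with median-of-ratios scaling, adjusted p = 5.04e-10). The loci of these runs were chosen after their values were seen.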

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

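The voom fits and both other ways to compute shares of reads were chosen after the data were seen; the other alternatives were fixed before. The balance of rises and falls depends on the scaling, and the size of the 2-fold counts on the scaling and the pseudocount. The number of genes changed was 7952, and only the stricter filter (mean of at least 5 FPKM) moved it past 1.5 times, to 5209, because it left 5557 genes to test. The number changed at least 2-fold was 1369. It became 2338 with a pseudocount of 0.1 and 2460 with voom on the recovered reads, both of which shrink low values less. With median-of-ratios scaling it was 783 and with quantile normalization 656, both of which remove the common shift. That shift was a median log2 change of -0.55 in the main fit and -0.66 with voom on the recovered reads. Of the calls, 87.0% were lower in luvangetin on the deposited scale, 49.6% with median-of-ratios scaling, 54.3% with quantile normalization and 49.7% with voom under median-of-ratios scaling. Neighbouring pairs that changed together numbered 263, and 703 with a pseudocount of 0.1, 476 with 0.5, 462 after rescaling to 1000000 per sample, 774 with voom, 127 with median-of-ratios scaling and 93 with quantile normalization, each time with a permutation p of 1e-04, the smallest possible. The rise in the read share of the top 100 genes was 10.2 percentage points, 9.96 as a share of summed FPKM and 10.7 when read numbers were divided by their common factor; the cause was not tested. Leaving out each sample in turn gave 7827 to 7861 genes changed, 1350 to 1404 changed at least 2-fold, 255 to 291 neighbouring pairs and 10.1 to 10.3 percentage points. The alternatives gave 168 values for 10 of the named loci. Of these values, 161 kept their direction and their side of the threshold, 5 reversed and 2 lost the call. The tally left out the other loci named above. Among those, FVEG_09122, FVEG_02993 and FVEG_11374 were called falls in an alternative, and FVEG_02331 lost its call. It included FVEG_11089, FVEG_13441, FVEG_02344 and FVEG_01856, which were picked for their large changes and so were unlikely to reverse. The 161 therefore does not describe named loci in general. FVEG_00316 reversed to 0.10 with median-of-ratios scaling, 0.22 with quantile normalization (a called rise) and 0.18 with voom under median-of-ratios scaling. FVEG_02006 reversed to 0.15 with median-of-ratios scaling and 0.15 with voom under that scaling. These alternatives remove the common shift by construction. Quantile normalization ended the call of FVEG_04512, since it gives the top rank the same value in every sample, and that of FVEG_02006 (-0.43), where the cause was not tested.

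The replicate number as a block gave 7932 genes changed and 1369 changed at least 2-fold, and 263 neighbouring pairs. Equal numbers did not pair the samples: the deviations of same-numbered samples from their group means correlated at 0.03, -0.00470 and -0.00971 across genes, and the labels name no shared culture or day. The planned count tests with edgeR and DESeq2 were not run, since the deposited values are FPKM; voom took their place. The planned tests of gene lists by product name could not be run, since no products were given. Depth limits what can be said of the 5416 listed genes below the filter.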

Other observations

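The tests of gene structure, of genes outside the most abundant ones, of length and of chromosome ends were chosen only after the results they bear on were seen. In the highest of 5 expression classes, genes with a larger inferred intron share tended to be lower under luvangetin. That share is the part of the annotated gene length outside the recovered exonic length. A difference between gene models would therefore count as intron. The class of genes was split into 4 by intron share, and the part with the least (median 0% of the gene model) had a median log2 change of -0.14, with 164 genes higher and 244 lower (limma). The part with the most (median 18.2%) had a median of -0.52, with 71 genes higher and 344 lower, and its genes were also shorter (median 1067 against 2333 exonic bases). Spearman's rho between intron share and log2 change across these 1744 genes was -0.22, and it was 0.02 in the class with the lowest expression. Genes are not independent replicates, and exonic length correlated with log2 change too (rho 0.16), so intron share and length were not separated.

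Some genes had reads in a single group. There were 15 genes with reads in all 3 luvangetin samples and none in untreated samples, and 84 with the opposite pattern. FVEG_13135, chosen after its values were seen, had 49 to 74 reads per luvangetin sample, 189 in all, and 0 untreated, at least 63-fold higher against a floor of 3 reads per group. The highest total among the 84 was 28 reads.

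On the deposited scale most genes were lower, while 68 of the 100 genes with most reads rose. This did not extend to the whole highest of 10 expression classes, where 306 rose and 525 fell. A candidate explanation is library composition, in which abundant genes take more of the reads and lower all others by a common factor. After median-of-ratios scaling 74.0% of 8618 genes outside the 100 with most reads were still called (limma), 3173 higher and 3203 lower. Centring fixes that even split, and the calls show only changes beyond a common factor. The same 100 genes held 40.9% of the library totals in untreated and 51.7% in luvangetin samples, so the other genes together held a smaller share. Whether composition accounts for the whole shift stays open. Gene length is argued against as the cause of the fall across all tested genes, since the highest median log2 change among 8 length classes was -0.44, near the overall -0.55. In the highest of 5 expression classes exonic length correlated with log2 change (Spearman's rho 0.16), so for abundant genes length stays open. Duplicate reads or saturation that raise every abundant gene stay open, because 29 of the 100 genes with most reads fell on the deposited scale but 8 were lower after median-of-ratios scaling, so the count rests on the scaling. A biological change of the treated mycelium stays open too, since FPKM values without an added standard do not show the total amount of messenger RNA per cell.

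Neighbouring genes that changed together may reflect shared local regulation, as in clusters of secondary metabolism, which is a hypothesis here. Shared reads of overlapping or adjoining gene models are argued against as the whole cause: pairs more than 1000 bases apart held 1.53 times the same-direction pairs of reassigned calls (permutation p = 1e-04), and 3.30 times with median-of-ratios scaling. The common shift cannot be weighed by this test, since reassigned calls keep the numbers of rises and falls that the shift gives. The excess was 3.16 times after median-of-ratios scaling (permutation p = 1e-04, the smallest possible), so it was not limited to the deposited scale. Reads shared between near-identical tandem copies were not tested, since no sequences were used here.

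Genes near chromosome ends changed more often in both directions. Of 423 tested genes among the 100 nearest to an end in gene order, 6.38% rose at least 2-fold, against 1.96% of 8232 elsewhere, and 19.6% fell against 13.2%. Low mean expression over both groups is argued against for the rises. They were 3.21 times those of calls reassigned within 10 expression classes (permutation p = 1e-04). Those classes rest on the luvangetin values too, so low expression in untreated mycelium was not tested and stays open. Chance placement of clustered calls is argued against, since the rises were 2.95 times those of calls rotated along the genome (permutation p = 1e-04). On the deposited scale the excess was weaker for the falls. It was 1.49 times calls reassigned within expression classes (permutation p = 1e-04) and 1.45 times rotated calls (permutation p = 0.012). With median-of-ratios scaling 13.2% rose near the ends and 5.89% elsewhere, and 5.91% fell near the ends and 2.55% elsewhere. Under that scaling the rises were 2.11 times and the falls 2.19 times rotated calls (permutation p = 1e-04 and 0.0218). Against calls reassigned within expression classes they were 2.56 and 2.09 times (permutation p = 1e-04 and 0.0005). Which direction was in larger excess thus rested on the scaling and the comparison. A regional effect of chromatin may be involved, but no data here bear on it, and the limit of 100 genes was set after the values were seen.

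Other splits of the 6 samples were used to ask whether chance could give such counts. The real split gave 7952 genes changed and 1369 changed at least 2-fold, and the highest of the other 9 splits gave 0 in both (limma), with 8 genes and 1 gene at an unadjusted p under 0.05. The real split was thus 1 of 10 with counts as large, and 10 splits are too few for a share under 0.05.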
